A study of Homo sapiens with 17 samples.

How the data were processed

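Poly A+ RNA was linearly amplified by a modified T7 method and sequenced strand-specifically as single reads of 42 cycles, per the labels, from cells sorted by MACS and FACS. The cores were not sorted after growth and HUVEC RNA was purchased. Per the submitters' processing notes, reads were processed with Bowtie and RSEM on hg18, also called NCBI36. The deposited expected counts are the values the authors made with RSEM, summed per gene and not scaled. The deposited TPM are the values the authors made with RSEM from the same reads, scaled within each library. Columns were matched to samples by the description given with each sample, and all 17 libraries were used. The files cover 18969 genes. No new alignment was done, and reads of mouse OP9 cells were not analysed here.

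Expected counts were rounded and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by group with a minimum count of 10, which kept 14780 genes, and the quasi-likelihood F-test with 1 coefficient per group. Only the 2 duplicated groups give residual spread, with 2 degrees of freedom, and the common dispersion was 0.134 with 4.16 prior degrees of freedom. A lone library was assumed to vary like the duplicated groups. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 26 lists per comparison, some of which share members. At the preset correlation camera's p-values rest on spread between genes and not on replication. With the estimated correlation they rest on the 2 residual degrees of freedom, which makes it hard for any list to pass. Each SE was worked back from the log2 fold change and the F statistic of edgeR's test. It is thus not a spread between the libraries of a group, and a lone library adds no spread of its own to it. Counting intervals are exact binomial intervals at 95%. Comparisons of 1 library with 1 library used log2 ratios of CPM with TMM scaling and a prior count of 2, and list medians were placed among 10000 random lists matched on mean expression. That placing takes no account of spread between libraries, so medians were set beside those within the duplicates, which was chosen after seeing the data.

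Except where the text says that a choice came later, the 14 comparisons, the tests, the lists and the alternatives were fixed before the data were examined. So was the rule for named genes. In tested comparisons it took genes that passed with at least 10 TPM in the higher group and no overlap between groups, and in the others genes that met the size rule with at least 50 TPM in the higher library, by size of change, of which the first 5 per direction are printed. List members could be named in any comparison whether they passed or not, and which of them to print was decided after the values were seen, as were the genes marked so in the text. Genes linked to sex, and symbols without a gene name, were passed over.

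The method was tried on simulated counts with known changes, made only in genes with at least 100 expected counts. Simulated spread followed mean expression alone, without the differences in spread between genes that real libraries have. The shares recovered can thus overstate what the tests find in these data. For AHP against HVMP it recovered 6% of 2-fold, 54% of 4-fold and 100% of 8-fold changes, with 3 false calls among 133. For HVMP against KDR-dim mesoderm it recovered 4%, 26% and 80%, with 4 false calls among 109. A list raised on purpose was called in both and 0 of 20 random lists were. Simulated genes were drawn independently of each other, so this does not show how often camera would call lists of correlated genes. For 1 library against 1, the size rule recovered 12%, 50% and 92%, and 145 of the 271 genes that met it were unchanged. Alternatives used DESeq2 1.42.0, limma and other filters, scalings, priors and sets of libraries. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 drew the figures. Pairing of the duplicates by replicate number was examined only as an alternative, because the labels do not say that replicate numbers mark a shared culture.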

Results

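RNA was sequenced from 17 libraries in 15 groups, made from the human embryonic stem cell line H1, from cells that differentiated from H1 on the mouse stromal line OP9, and from purchased RNA of human umbilical vein endothelial cells (HUVEC). The series followed mesoderm on its way to hemogenic endothelium, the endothelium that gives rise to blood. The groups were undifferentiated H1, posterior mesoderm of day 3 (sorted on APLNR), and from day 4 the KDR-dim mesoderm, the hematovascular mesodermal precursors (HVMP, KDR-bright) and the KDR-bright VE-cadherin-positive cells. From day 5 came hemogenic endothelial progenitors (HEP, CD73-negative), non-hemogenic endothelial progenitors (non-HEP, CD73-positive), angiogenic hematopoietic progenitors (AHP, CD43-low and CD235a-positive) and CD41a-positive cells. From day 8 came CD43-positive cells that carried CD235a or CD41a, and CD45-negative and CD45-positive progenitors that carried neither. Endothelial cores were taken after 3 days on OP9 and 3 days in semisolid medium, and H1-derived endothelial cells at passage 2. The labels give HVMP and posterior mesoderm as EMHlin-negative. HVMP and AHP had 2 libraries each and the other groups 1.

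Total expected counts were 19294496 in HVMP replicate 1, 8642345 in HVMP replicate 2, 18972314 in AHP replicate 1 and 7200809 in AHP replicate 2. They were 16990513 in undifferentiated H1, 7191638 in posterior mesoderm, 15867237 in KDR-dim mesoderm, 8172894 in the VE-cadherin-positive cells and 15294574 in the cores. They were 7105114 in HEP, 6574379 in non-HEP, 18458585 in the day 5 CD41a-positive cells and 16023527 in the day 8 CD235a/CD41a-positive cells. CD45-negative progenitors had 8349581, CD45-positive progenitors 7049353, passage 2 endothelial cells 2923484 and HUVEC 7757577. The libraries thus fell into a deep set of 7 and a shallow set of 10, and each pair of duplicates had its replicate 1 in the deep set and its replicate 2 in the shallow set. The column headers also name different sort markers within each pair: that of HVMP replicate 2 says CD31-negative and that of replicate 1 does not name CD31, and that of AHP replicate 1 names CD235a and CD41a where that of replicate 2 names CD31 and CD73. Nothing in the labels says that duplicates came from separate cultures, so edgeR's p-values for genes measure only the spread between libraries, which may be technical. Camera's p-values at the preset correlation measure spread between genes instead. Counting intervals and floors cover counting error only.

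Transcripts of sorted surface proteins were set beside the sorts. NT5E, which encodes CD73, stood at 65.7 TPM in non-HEP and 7.94 TPM in HEP. KIT, which encodes CD117, was 66.8 TPM in non-HEP, labelled high, 38.5 TPM in HEP, labelled intermediate, and 3.00 and 3.84 TPM in AHP, labelled negative. PTPRC, which encodes CD45, was 40.1 TPM in CD45-positive and 1.39 TPM in CD45-negative progenitors. The HVMP libraries differed from each other in the genes of VE-cadherin and CD34: CDH5 was 51.3 TPM in replicate 1 and 0.63 TPM in replicate 2, and CD34 was 73.3 and 2.53 TPM. PDGFRA followed the labels less closely: it was 32.2 and 61.7 TPM in HVMP, labelled low or negative, and 64.3 TPM in posterior mesoderm, labelled positive. HBA1 and HBA2 share near-identical sequence, as do HBG1 and HBG2, so how reads were split within each pair is uncertain.

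**Figure D1:**
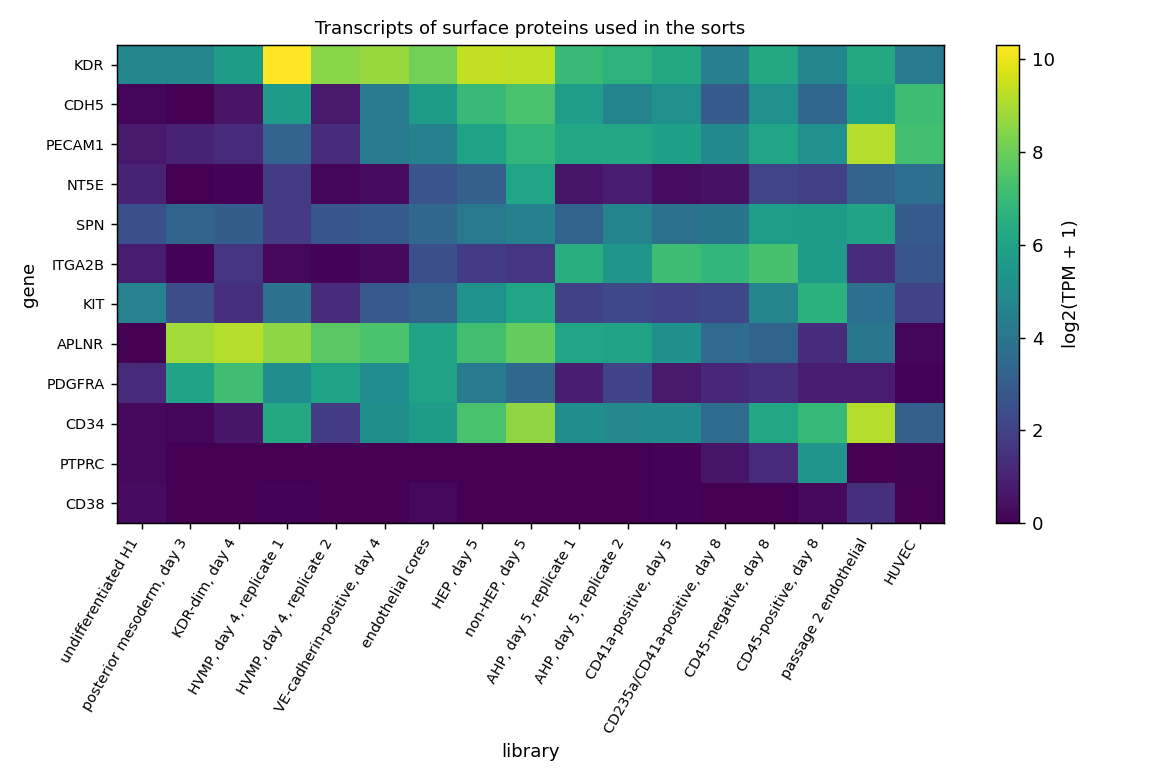
Level of transcripts of sorted surface proteins in each of the 17 libraries, as log2(TPM + 1), with genes in rows and libraries in columns. KDR was highest in HVMP replicate 1, at 1261 TPM, and PTPRC reached 40.1 TPM in the CD45-positive progenitors.

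AHP were compared with HVMP, the day 4 precursors, to ask which transcripts separate early blood progenitors from the mesoderm before hemogenic endothelium. ITGB3, GATA1, HBE1 and RUNX1 were among 218 genes that rose in AHP and HAND1, HOXA9 and BMP4 among 468 that fell, 686 of 14780 genes tested (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, smallest adjusted p = 0.0127). ITGB3, which encodes a platelet integrin chain, was at least 178-fold higher in AHP, with 19.58 and 19.03 TPM against 0 in both HVMP libraries. HBA2 was at least 54.6-fold higher, and the blood transcription factor genes GATA1 and GFI1B at least 40.5-fold and 35.2-fold higher, with floors of 3 counts per library. P2RX1, the gene of an ATP-gated channel, had 1025 counts in AHP and 1 in HVMP, a ratio of 959 with a 95% counting interval from 172 to 37905. The embryonic globin gene HBE1 rose by 7.97 ± 1.01 on the log2 scale (SE, n = 2 and 2), from 1.38 and 10.3 TPM to 989 and 1961 TPM. RUNX1, the gene of the factor that starts blood formation, rose by 5.30 ± 1.06, from 4.85 and 0.52 TPM to 167 and 98.7 TPM (edgeR adjusted p = 0.0485). MYB rose by 4.03 ± 0.48 and the erythroid factor gene KLF1 by 4.30 ± 0.69.

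Among the genes that fell in AHP, FOXF2, a mesenchymal transcription factor gene, was at least 61.4-fold lower. FGF19, a growth factor gene, had 3 counts in AHP and 2232 in HVMP, a ratio of 795 with a 95% counting interval from 272 to 3860.0. HOXC6 fell by 8.62, the channel gene TRPA1 by 8.16 and the fatty acid binding protein gene FABP7 by 7.64 on the log2 scale. HAND1, a gene of lateral plate mesoderm, fell by 4.92 ± 0.76, from 1522 and 4516 TPM to 59.6 and 166 TPM. HOXA9, which marks posterior identity, fell by 6.16 ± 0.61, from 101 and 48.2 TPM to 0.87 and 1.5 TPM. PDGFRA fell by 4.75 ± 0.76, BMP4 by 5.78 ± 0.54 and ETV2, an early endothelial factor gene, by 4.13 ± 0.77. The BMP target genes ID1 and ID3 fell by 2.51 ± 0.34 and 3.70 ± 0.52. KDR did not pass, at -2.95 ± 0.62 (edgeR adjusted p = 0.0549), nor did PECAM1 at 3.68 ± 0.77 (edgeR adjusted p = 0.0555). Without HVMP replicate 1 the count was 1379, and without HVMP replicate 2 it was 1383. DESeq2 called 1167 genes and limma 169, of which 46.2% were higher in AHP in place of 31.8%. With a block for replicate number edgeR called 2971, 42.3% of them higher, but the labels do not say that libraries with the same replicate number belong together. Replicate number also splits these libraries as the depth set does, so the block cannot be told from the depth set. A size rule, which takes genes that differ at least 4-fold with at least 50 counts in the higher library, was met by 1150 genes between AHP replicate 1 and HVMP replicate 1 within the deep set, and by 958 between the replicates 2 within the shallow set.

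Gene lists written before the data were examined moved with these genes. Of 20 erythroid genes tested 13 passed, 13 higher and 0 lower, and 19 were higher when adjusted over the list alone. Their median was 6.98 log2 as fitted and 5.56 as a bounded median, which sets genes at 0 counts in a group at their lower bound and genes at or under the floor in both groups at 0. Camera, which tests a list against the other genes at a preset correlation of 0.01, gave the erythroid list an adjusted p of 2.07e-15, and adjusted p = 0.297 with an estimated correlation. The former rests on spread between genes. The latter also rests on the 2 residual degrees of freedom, so it need not reflect correlation between genes alone. For this list the estimated correlation was 0.086. The hematopoietic factor list had a median of 3.20 and a bounded median of 2.66, with 7 of 13 genes higher, 10 when adjusted over the list alone (camera adjusted p = 9.15e-07). The megakaryocyte list had a median of 3.27 with 6 of 14 higher, 8 over the list alone (1.4e-06). Lateral plate mesoderm fell, with a median of -4.32 and 8 of 14 genes lower, 13 over the list alone (8.37e-08). The HOXA cluster had a median of -6.16 with 7 of 10 lower, 9 over the list alone (8.37e-08), and the HOXB cluster -1.66 with 3 of 8 lower, 5 over the list alone (0.000828). BMP and SMAD targets had a median of -2.34 with 5 of 10 lower, 10 over the list alone (2.44e-06). For each of these lists the camera adjusted p with an estimated correlation was 0.297, and within the depth sets the medians had the same signs, such as 5.76 and 4.99 for erythroid genes and -5.29 and -4.85 for the HOXA cluster. The estimated correlation was 0.44 for lateral plate mesoderm and 0.489 for BMP and SMAD targets. It was 0.084 for hematopoietic factors, -0.057 for megakaryocyte genes, and 0.141 and 0.211 for the HOXA and HOXB clusters. Where it lay above the preset 0.01, camera's p-values at the preset assume less correlation than was estimated.

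The other lists that camera called at the preset correlation were smaller or mixed. Mesenchyme had a median of -1.24 (camera adjusted p = 6.92e-05), genes tied to hematopoietic stem cells, which include HOXA members, -1.99 (0.00169), trophoblast and epithelial genes -1.02 (0.0483) and proliferation genes -0.49 (0.0106). Myeloid genes had a median of 2.22 and a bounded median of 0.85 (0.000828), and lymphoid genes 2.99 and 1.21 (0.0166). Primitive streak genes had -2.17 and a bounded median of 0 (0.00909), and neural genes -3.69 and -0.59 (0.0166). With an estimated correlation the adjusted p was 0.404 for the myeloid list and 0.297 for the rest. Camera did not call 11 lists. The endothelial list, with a median of 0.42 and 1 of 20 genes lower (FLT1, -1.77 ± 0.33), had a camera adjusted p of 0.371, and its medians were -0.46 in the deep set and 2.09 in the shallow set. The others were hematovascular factors (median 0.13, camera adjusted p = 0.461), arterial and Notch genes (-1.09, 0.0579), venous and lymphatic genes (-0.56, 0.719), pluripotency (-0.44, 0.656), paraxial mesoderm (0.28, 0.955), endoderm (0.70, bounded 0, 0.153), hypoxia (0.01, 0.955), interferon (0.20, 0.236), immediate early genes (-0.54, 0.188) and sort genes (-0.22, 0.562).

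**Figure D2:**
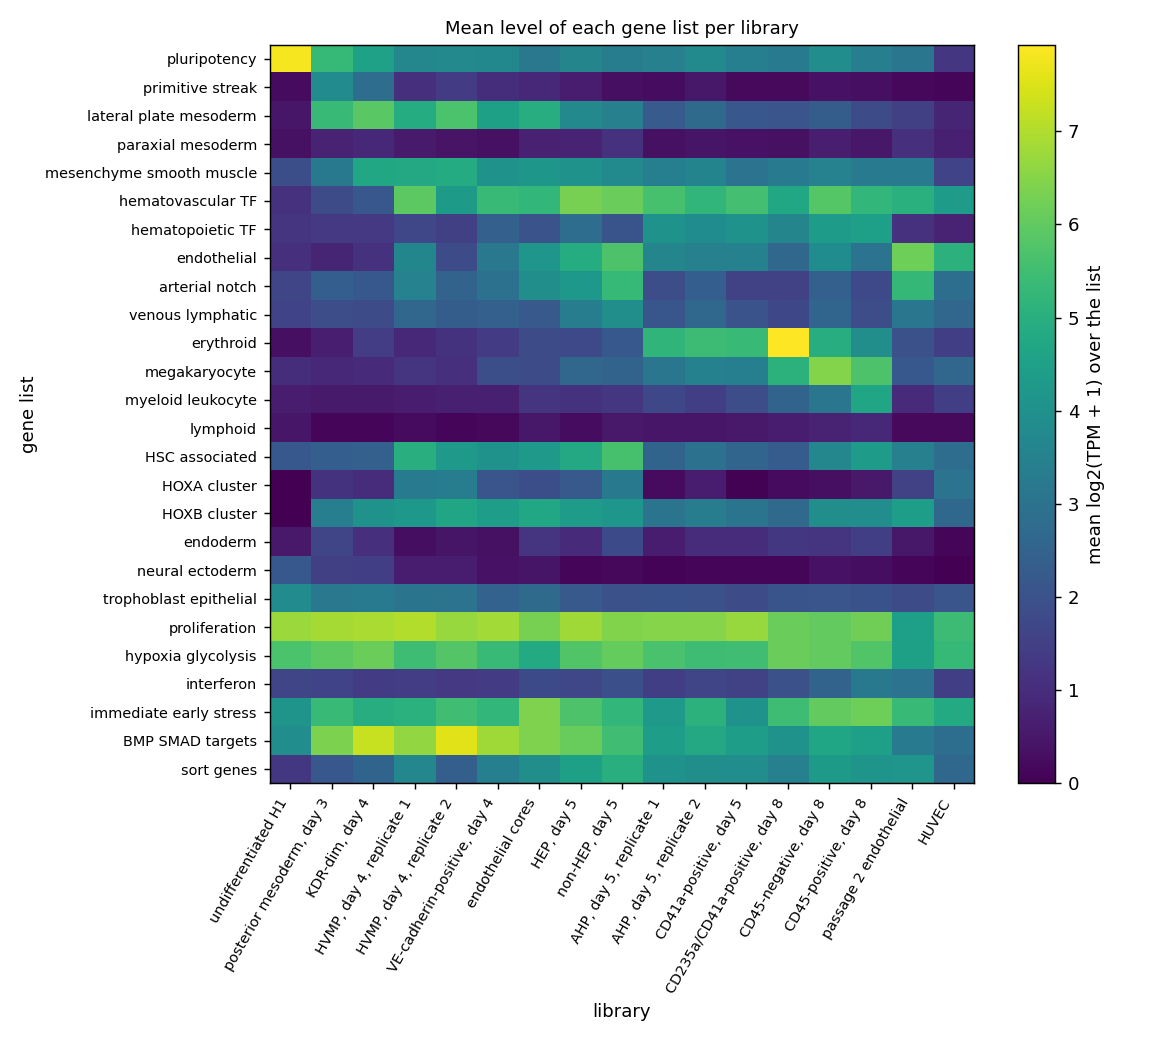
Mean log2(TPM + 1) of each of the 26 gene lists in each of the 17 libraries, with lists in rows and libraries in columns. The pluripotency list was highest in undifferentiated H1, at 7.83.

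HVMP were compared with KDR-dim mesoderm of the same day, a subset that the labels give as lacking blood potential, to ask what marks the KDR-bright cells. Transcription factor genes of the hematovascular program stood higher in HVMP by value: TAL1 at 6.37 ± 0.85, LMO2 at 4.61 ± 0.68 and FLI1 at 4.51 ± 0.76 log2 (SE, n = 2 and 1). HOXA9 differed by 7.42 ± 0.90 and KDR by 4.11 ± 0.88. Genes of the primitive streak stood lower in HVMP, with EOMES at -4.02 ± 0.85 and T at -3.76 ± 0.78, as did CER1, a gene of the endoderm list, at -7.63 ± 0.93. No single gene passed as fitted: edgeR's quasi-likelihood test called 0 genes (smallest adjusted p = 0.236, 1220 genes at unadjusted p under 0.05), DESeq2 called 235 and limma 21. Without HVMP replicate 1 the count was 225 and without replicate 2 it was 394, and with the depth set as a term, added after seeing the data, it was 653. Between HVMP replicate 1 and KDR-dim mesoderm, within the deep set, 763 genes met the size rule (4-fold and 50 counts), 409 higher and 354 lower in HVMP. With HVMP replicate 2, of the shallow set, the balance turned, with 208 higher and 276 lower. Direction also depended on the method: 83.4% of the DESeq2 calls were higher in HVMP, and 0% of the limma calls.

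The hematovascular factor list had a median of 4.61 over 13 genes, of which 11 passed when adjusted over the list alone and 0 over all genes tested (camera adjusted p = 1.28e-10, adjusted p = 0.559 with an estimated correlation). HOXA genes had a median of 4.44 and a bounded median of 3.17, with 7 of 10 higher over the list alone (camera adjusted p = 1.31e-07, adjusted p = 0.415 with an estimated correlation). Primitive streak genes had a median of -4.02 and a bounded median of -3.76, with 7 of 11 lower and 1 higher over the list alone (camera adjusted p = 1.13e-08, adjusted p = 0.415 with an estimated correlation). With HVMP replicate 1, in the deep pair, the medians were 4.99, 3.16 and -3.70, and with replicate 2 they were 3.37, 2.92 and -3.26. Endothelial genes depended most on the HVMP library, with a median of 4.06 with replicate 1 and 1.05 with replicate 2. At the preset correlation camera called 11 lists in all. Among them, genes tied to hematopoietic stem cells, which include HOXA members, had a median of 3.07, with 9 of 14 higher over the list alone (camera adjusted p = 2.64e-06, adjusted p = 0.415 with an estimated correlation).

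HVMP were compared with the posterior mesoderm of day 3, to ask what separates the day 4 KDR-bright cells from APLNR-positive mesoderm a day earlier. TAL1 differed by 7.38 ± 0.92 log2, FLI1 by 6.31 ± 0.86 and LMO2 by 5.23 ± 0.72 (SE, n = 2 and 1), and ETV2 was at least 21.6-fold higher in HVMP. The fibrillar collagen gene COL3A1 differed by 5.28 ± 0.80. In the other direction EOMES stood at -5.92 ± 0.90, T at -4.55 ± 0.80, and CER1, of the endoderm list, at -9.90 ± 0.98, from 367 TPM in posterior mesoderm to 0.54 and 0 TPM. No single gene passed as fitted: edgeR called 0 (smallest adjusted p = 0.109, 1660 at unadjusted p under 0.05), DESeq2 411 and limma 125. Without HVMP replicate 1 edgeR called 321 genes and without replicate 2 it called 998, and with the depth set as a term, added after seeing the data, 476. Between HVMP replicate 2 and posterior mesoderm, within the shallow set, 576 genes met the size rule (4-fold and 50 counts), 335 higher and 241 lower in HVMP. The direction of the calls turned with the method: 78.3% of the DESeq2 calls were higher in HVMP, and 11.2% of the limma calls.

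Primitive streak genes had a median of -5.46 and a bounded median of -5.28, with 10 of 11 lower and 1 higher when adjusted over the list alone (camera adjusted p = 3.85e-10, adjusted p = 0.432 with an estimated correlation). Hematovascular factors had a median of 5.23 and a bounded median of 4.43, with 10 of 13 higher over the list alone (camera adjusted p = 3.21e-09, adjusted p = 0.432 with an estimated correlation). Mesenchymal genes had a median of 1.78, with 7 of 14 higher over the list alone (camera adjusted p = 5.17e-06, adjusted p = 0.432 with an estimated correlation). Over all genes tested 0 of these list members passed. In the shallow pair the medians were -4.25, 3.31 and 1.41, and with HVMP replicate 1 they were -4.54, 5.53 and 1.75. Endothelial genes had a median of 4.91 and a bounded median of 3.49 and depended on the HVMP library, at 1.64 with replicate 2 and 4.74 with replicate 1. Camera called 12 lists in all at the preset correlation, and not all are given here.

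The KDR-bright VE-cadherin-positive cells of day 4, labelled as pan-endothelial progenitors, were compared with HVMP to ask what accompanies VE-cadherin on the same day. Blood factor genes stood higher in the VE-cadherin-positive cells: RUNX1 by 3.04 ± 1.05 log2, MYB by 2.36 ± 0.51, GFI1 by 1.53 ± 0.42 and IKZF1 by 1.38 ± 0.40 (SE, n = 1 and 2). HVMP replicate 1 differed from replicate 2 by 3.22 log2 in RUNX1, so that value depends on the HVMP library. For MYB, GFI1 and IKZF1 the replicates differed by 1.11, 0.31 and -0.42. The HOXA gene HOXA10 stood at -1.97 ± 0.84 and the matrix gene LUM at -1.50 ± 0.44. BMP2, a growth factor gene chosen after its value was seen, stood at -2.53 ± 0.64. No single gene passed as fitted: edgeR called 0 (smallest adjusted p = 1, 300 at unadjusted p under 0.05), DESeq2 7 and limma 0. Without HVMP replicate 1 edgeR called 57 genes and without replicate 2 it called 38, and with the depth set as a term, added after seeing the data, 0. CDH5, the gene of VE-cadherin, was 17.5 TPM, between the 51.3 and 0.63 TPM of the HVMP libraries, and the column header of these cells names CD31, not VE-cadherin. Against HVMP replicate 2, within the shallow set, 167 genes met the size rule (4-fold and 50 counts), 104 higher and 63 lower. Against HVMP replicate 1, of the deep set, the balance turned, with 125 higher and 167 lower.

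By list, hematopoietic factors had a median of 0.93 with 5 of 13 higher when adjusted over the list alone and 0 over all genes (camera adjusted p = 3.9e-05, adjusted p = 0.391 with an estimated correlation). The HOXA cluster had a median of -1.98 and a bounded median of -1.74, with all 10 genes below 0 and 0 passing either way (camera adjusted p = 6.27e-06, adjusted p = 0.391 with an estimated correlation). In the shallow pair these medians were 1.07 and -1.78. Mesenchymal genes had a median of -0.83, with 13 of 14 below 0 (camera adjusted p = 2e-04, adjusted p = 0.391 with an estimated correlation). Camera also called 3 lists that kept their sign against replicate 2 and replicate 1. These were megakaryocyte genes at 0.91 and 1.01, trophoblast and epithelial genes at -0.77 and -0.71, and genes tied to hematopoietic stem cells at -0.56 and -0.91. Some lists turned or vanished with the HVMP library: against replicate 2 and replicate 1, endothelial genes had medians of 1.86 and -0.62, hematovascular factors 1.21 and -0.49, and lateral plate genes, which camera also called, -1.52 and -0.04.

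AHP were compared with HEP of the same day, to ask how the CD43-low blood progenitors differ from hemogenic endothelium. Red cell genes stood higher in AHP: HBE1 by 7.02 ± 1.33 log2 and KLF1 by 3.75 ± 0.92 (SE, n = 2 and 1), while GATA1 was at least 28.5-fold higher. The platelet integrin gene ITGA2B differed by 4.89 ± 0.78. Arterial and posterior genes stood lower in AHP, with SOX17 at -4.94 ± 1.68, the Notch ligand gene DLL4 at -3.88 ± 1.11, HOXA9 at -5.07 ± 0.62 and HOXA10 at -4.38 ± 0.81. The stem cell factor receptor gene KIT stood at -3.32 ± 1.05, and the endothelin gene EDN1, chosen after its value was seen, at -5.12 ± 1.24. No single gene passed as fitted: edgeR called 0 (smallest adjusted p = 0.172, 1194 at unadjusted p under 0.05), DESeq2 292 and limma 0. Without AHP replicate 1 edgeR called 25 genes and without replicate 2 it called 1, and with the depth set as a term, added after seeing the data, 317. Between AHP replicate 2 and HEP, within the shallow set, 393 genes met the size rule (4-fold and 50 counts), 79 higher and 314 lower in AHP.

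Erythroid genes had a median of 6.22 and a bounded median of 4.59, with 16 of 20 higher when adjusted over the list alone (camera adjusted p = 1.98e-16, adjusted p = 0.362 with an estimated correlation). The HOXA cluster had a median of -4.29 and a bounded median of -4.01, with 7 of 10 lower over the list alone (camera adjusted p = 1.04e-08, adjusted p = 0.421 with an estimated correlation). Arterial and Notch genes had a median of -2.59 with 4 of 14 lower over the list alone (camera adjusted p = 2.66e-07, adjusted p = 0.430 with an estimated correlation), and endothelial genes -1.55 with 4 of 20 lower (camera adjusted p = 1.5e-05, adjusted p = 0.531 with an estimated correlation). Over all genes tested 0 of these list members passed. In the shallow pair the medians were 4.61, -2.69, -2.05 and -1.73. The estimated correlations were 0.013, 0.217, 0.306 and 0.764, against the preset 0.01. Camera called 14 lists in all at the preset. Among the others, genes tied to hematopoietic stem cells, which include HOXA members, had a median of -2.43, with 9 of 14 lower over the list alone. Hematopoietic factors had 1.44, with 3 of 13 higher. For both, camera gave adjusted p = 2.92e-06, and 0.421 with an estimated correlation.

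The day 5 CD41a-positive cells were compared with AHP, which lack CD41a, to ask what accompanies that platelet integrin. These populations were close: the CD41a-positive library and AHP replicate 1 had the highest correlation across genes of all 136 pairs of libraries (Pearson r = 0.986), although genes are not independent replicates. ITGA2B, which encodes CD41a, stood at 1.09 ± 0.56 log2 (SE, n = 1 and 2), with 135 TPM against 86.6 and 43.1 TPM. Among genes chosen after their values were seen, the endosomal gene RAB5C stood at 2.36 ± 0.44 and the splicing gene HNRNPL at -2.03 ± 0.39. TMSB4X was 1.35 TPM against 812 and 1559 TPM, but it has near-identical copies and its level ranged from 1.35 to 21420 TPM over the 17 libraries. No single gene passed as fitted: edgeR called 0 (smallest adjusted p = 1, 117 at unadjusted p under 0.05), DESeq2 1 and limma 0. Without AHP replicate 1 edgeR called 2 genes, and without replicate 2 or with the depth set as a term, added after seeing the data, it called 0. Against AHP replicate 1, within the deep set, 33 genes met the size rule (4-fold and 50 counts).

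Myeloid genes had a median of 0.66 and a bounded median of 0.49, with 15 of 16 above 0 (camera adjusted p = 1.81e-06, adjusted p = 0.471 with an estimated correlation), and 0.29 in the deep pair. The HOXA cluster had a median of -3.59 but a bounded median of -0.72, and -0.74 in the deep pair (camera adjusted p = 1.85e-06, adjusted p = 0.471 with an estimated correlation). In both lists 0 genes passed over all genes tested or when adjusted over the list alone. Camera called 8 lists in all at the preset correlation, and only these are given here.

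Endothelial cores, which the labels place within hemangioblast colonies, were compared with HVMP to ask how endothelium grown in semisolid medium differs from the sorted precursors. The endothelial genes EMCN and CLDN5 stood higher in the cores, by 5.49 ± 0.95 and 5.05 ± 0.75 log2, and so did ITGA2B by 5.05 ± 0.71 (SE, n = 1 and 2). TAL1 stood lower in the cores at -3 ± 0.70, HOXA10 at -3.35 ± 0.91 and the keratin gene KRT8 at -3.54 ± 0.62. Among genes chosen after their values were seen, the imprinted gene DLK1 stood at 5.12 ± 0.43, the cell cycle inhibitor gene CDKN1A at 4.80 ± 0.53 and the neurexophilin gene NXPH2 at -5.69 ± 0.58. As fitted, edgeR called 0 genes (smallest adjusted p = 0.179, 2253 at unadjusted p under 0.05), DESeq2 301 and limma 11, but with the depth set as a term, added after seeing the data, edgeR called 2438. Without HVMP replicate 1 it called 522 genes and without replicate 2 it called 342. Against HVMP replicate 1, within the deep set, 874 genes met the size rule (4-fold and 50 counts), 606 higher and 268 lower in the cores. Of the DESeq2 calls 40.5% were higher in the cores, and of the limma calls 90.9%.

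The HOXA cluster had a median of -2.60, with 3 of 10 lower when adjusted over the list alone (camera adjusted p = 0.00789, adjusted p = 0.496 with an estimated correlation). Endoderm genes had a median of 4.52 and a bounded median of 2.61, with 4 of 9 higher over the list alone (camera adjusted p = 0.00799, adjusted p = 0.496 with an estimated correlation), and TTR among them was at least 10.0-fold higher. The endoderm median had the other sign, -0.55, with a stricter filter on low counts. Immediate early genes had a median of 1.01 with 1 of 13 higher over the list alone (camera adjusted p = 0.0115, adjusted p = 0.496 with an estimated correlation). In the deep pair these medians were -2.17, 2.68 and 1.16. Over all genes tested 0 of these list members passed. Endothelial genes differed by library, with a median of 0.02 against HVMP replicate 1 and 3.82 against replicate 2. Camera called 10 lists in all at the preset correlation, and not all are given here.

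**Figure D3:**
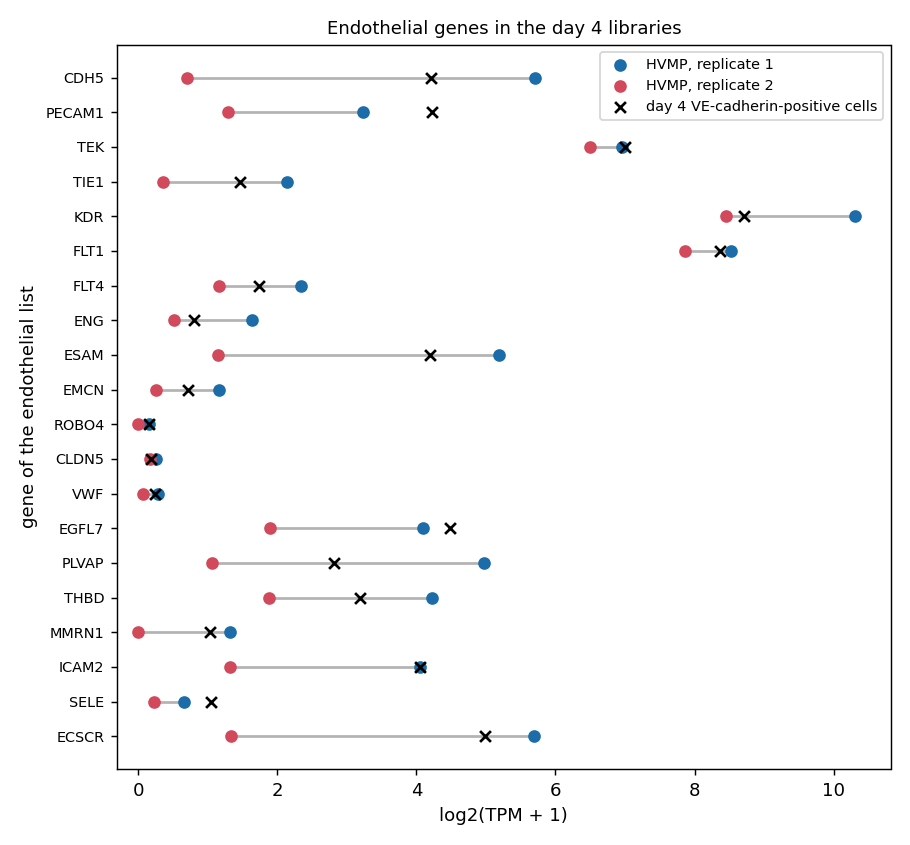
Level of the 20 genes of the endothelial list as log2(TPM + 1) in the 2 HVMP libraries (filled points, joined by a line) and in the VE-cadherin-positive cells of day 4 (crosses). All 20 genes were higher in HVMP replicate 1 than in replicate 2.

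The remaining comparisons had 1 library on each side, so they had no replicate check and were described by the size rule of at least 4-fold and at least 50 counts in the higher library. As a yardstick, 353 genes met it between the HVMP duplicates and 286 between the AHP duplicates. Both pairs cross the depth sets and their headers name different sort markers. The yardstick is therefore unlike a comparison within a depth set, and falling under it does not show that 2 populations are the same. List medians were set beside the size of the same list's median difference within the HVMP and the AHP duplicates, a yardstick chosen after seeing the data.

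Posterior mesoderm was compared with undifferentiated H1, to describe the start of the path. HAND1 was 2276 TPM in posterior mesoderm and had 1 count in H1, a ratio of 33721 with a 95% counting interval from 6051 to 1332010. APLNR was at least 5384-fold, GATA6, an early mesendoderm factor gene, at least 2032-fold and the neuropeptide gene GRP at least 892-fold higher in posterior mesoderm. EOMES had 1997 counts in posterior mesoderm and 2 in H1, a ratio of 2245 (621 to 18547). The pluripotency genes SOX2, NANOG and POU5F1 stood at -6.88, -4.17 and -3.48 log2, and POU5F1 went from 808 to 74.2 TPM. SOX3 stood at -6.48, IDO1 was at least 142-fold lower, and CLDN4 and CXCL6 had ratios of 460 (82.4 to 18186) and 247 (84.2 to 1197) in favour of H1. Over the list, primitive streak genes had a median of 6.15, lateral plate mesoderm 5.96, HOXB genes 6.48 with a bounded median of 6.42, and pluripotency genes -2.27. Within the HVMP and AHP duplicates the sizes were 0.29 and 0, 0.98 and 0.64, 0.64 and 0.06, and 0.19 and 0.41. The size rule was met by 1410 genes, 475 higher and 935 lower in posterior mesoderm, and these libraries belong to different depth sets.

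HEP were compared with the VE-cadherin-positive cells of day 4, a day earlier, to describe how they differed. The sort differed as well as the day: the labels give HEP as lacking CD73, CD235a and CD43, and the day 4 cells as KDR-bright. Higher in HEP were CD93, a surface lectin gene, by 4.32 log2 (73.7 against 2.87 TPM), the lipase gene LPL by 3.91, the caveolin gene CAV1 by 3.88 and RNASE1 by 3.01. So was VPS24, by 3.66, but a read-through symbol covers it too and its reads are uncertain. The endothelial gene EMCN stood at 4.36 and CDH5 at 2.44, a ratio of 5.44 (95% counting interval 4.83 to 6.15). Within the HVMP and AHP duplicates, replicate 1 over replicate 2, CDH5 differed by 6.13 and 1.31 log2 and EMCN by 2.11 and -1.4. Lower in HEP were the cardiac actin gene ACTC1 at -3.60, the primitive streak gene CDX2 at -3.37, the lateral plate gene HAND1 at -3.30 and the keratin gene KRT8 at -3.08. The symbol DNAJC25-GNG10, a read-through of neighbouring genes whose reads are uncertain, was at least 198-fold lower in HEP. The endothelial list had a median of 1.67, with 19 of 20 genes above 0, and the arterial list 1.23. These exceeded the 0.13 and 0.69 within the AHP duplicates but not the 2.26 and 1.24 within the HVMP duplicates. Lateral plate mesoderm had -1.12, against sizes of 0.98 and 0.64 within the HVMP and AHP duplicates. The size rule was met by 215 genes, 161 higher and 54 lower in HEP, fewer than between either pair of duplicates. Those pairs cross the depth sets and these libraries do not. On log2(TPM + 1) 87.3% were higher in place of 74.9%.

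HEP were compared with non-HEP, to describe what separates endothelium labelled hemogenic from endothelium labelled non-hemogenic. GFI1, which encodes a repressor of the endothelial program, stood 4.41 log2 higher in HEP, a ratio of 23.2 (95% counting interval 13.4 to 44.1), at 34.0 against 1.49 TPM. RUNX1 was 50.6 against 23.8 TPM, a ratio of 2.18 (1.94 to 2.46), and MYB 55.4 against 16.3 TPM, a ratio of 3.39 (2.85 to 4.05). These intervals leave out spread between libraries. Within the HVMP and AHP duplicates, replicate 1 over replicate 2, RUNX1 differed by 3.22 and 0.9 log2, MYB by 1.11 and -0.05 and GFI1 by 0.31 and 0.25. The calcium sensor gene SCGN stood 3.06, BMPER 2.76, SMAD6 2.64 and the red cell gene RHAG 2.57 higher, as did PGAM4, which shares reads with close copies, by 3.49. Lower in HEP were NT5E, the sort gene, at -3.01, EMCN at -2.42, CXCR4 at -2.33 and SOX17 at -1.85. RBP4 stood at -2.92, STEAP1 at -2.91, DIO3 at -2.52 and HBE1 at -2.49. HOXA9 was 44.0 TPM in HEP and 132 TPM in non-HEP. The medians of endothelial and arterial genes were -0.78 and -1, with 17 of 20 and 13 of 14 below 0. In size they exceeded the 0.13 and 0.69 within the AHP duplicates but not the 2.26 and 1.24 within the HVMP duplicates. The HOXA cluster had -1.53, against 0.38 and 0.93 within the HVMP and AHP duplicates, and hematopoietic factors 0.64, against 0 and 0.22. Genes tied to hematopoietic stem cells went the other way, at -0.83 with 12 of 14 below 0, against 0.49 and 0.40. In all 96 genes met the size rule, 47 higher and 49 lower, against 353 and 286 between duplicates, which cross the depth sets as HEP and non-HEP do not.

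The CD235a/CD41a-positive cells of day 8 were compared with the CD41a-positive cells of day 5, to describe how they differed. The labels give the day 5 cells as VE-cadherin-positive with both CD235a and CD41a. They give the day 8 cells as CD34-positive with either marker and do not name VE-cadherin. Effects of the day and of the sort therefore cannot be told apart here. The platelet factor gene PF4 stood 6.96 log2 higher at day 8, at 1754 against 17.2 TPM. The red cell genes AHSP and SLC4A1 stood 6.51 and 6.23 higher, the matrix gene THBS1 5.58, and TMSB4X, whose reads are uncertain, 6.21. HBE1 was 29624 TPM at day 8 and 2117 TPM at day 5, and globin genes held 5.12% of TPM at day 8 against 0.317%. Lower at day 8 were CALCRL at -2.70, ENC1 at -2.39, MS4A3 at -2.29 and RGS5 at -2.07. Erythroid genes had a median of 3.09, megakaryocyte genes 2.30, myeloid genes 1.14 and immediate early genes 1.64, and endothelial genes had -0.64 with a bounded median of -0.57. Within the HVMP and AHP duplicates the sizes were 0.04 and 0.03, 0 and 0.55, 0 and 0.49, 0.7 and 0.99, and for endothelial genes 2.26 and 0.13. The size rule was met by 317 genes, 253 higher and 64 lower at day 8, and on log2(TPM + 1) 69.2% were higher in place of 79.8%.

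The CD235a/CD41a-positive cells of day 8 were compared with the CD45-negative progenitors of the same day, to set the erythro-megakaryocytic cells against multipotent cells. Globin and heme genes stood higher in the former: HBZ by 6.47 log2 (2263 against 38.9 TPM), AHSP by 5.79, the heme enzyme gene ALAS2 by 4.95, HBE1 by 4.90 and HBA1 by 4.85. Lower were CALCRL at -3.06, the desaturase gene SCD5 at -3.01, ASTN2 at -2.92, STAG3L1 at -2.89 and TMSB4X, whose reads are uncertain, at -3.21. The progenitor genes KIT, MECOM and HLF stood at -2.12, -2.14 and -2.93. PF4 was 1754 TPM against 5015 TPM, and the megakaryocyte list had a median of -0.94, against 0 and 0.55 within the HVMP and AHP duplicates, while the erythroid list had 4.04, against 0.04 and 0.03. The size rule was met by 304 genes, 134 higher and 170 lower, and these libraries belong to different depth sets. The split depended on the scale: on log2(TPM + 1) 16.2% were higher in place of 44.1%, and with the deep-minus-shallow difference removed, added after seeing the data, 606 genes met the rule.

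CD45-positive and CD45-negative progenitors of day 8 were compared to describe what accompanies CD45. PTPRC stood 4.81 log2 higher in the CD45-positive cells. Also higher were the factor gene IRF8 by 5.00, the granule gene MPO by 4.98 (287 against 9.24 TPM), RNASE2 by 4.09, the chemokine gene CCL2 by 3.52 and SNX10 by 3.37. The stem cell genes SPINK2 and HLF stood 2.77 and 2.16 higher, with HLF at 10.1 against 2.27 TPM. Lower were RGS5 at -2.52, MYL4 at -2.50, ALDH1A1 at -2.24, GSTA2 at -2.24 and the endothelial gene ECSCR at -2.21. The myeloid list had a median of 2.23, the erythroid list -1.27 and the interferon list 0.78, against 0 and 0.49, 0.04 and 0.03, and 0.41 and 0.16 within the HVMP and AHP duplicates. The arterial and endothelial lists, at -1.14 and -0.88, exceeded in size the 0.69 and 0.13 within the AHP duplicates but not the 1.24 and 2.26 within the HVMP duplicates. A total of 144 genes met the size rule, 90 higher and 54 lower, fewer than between either pair of duplicates. Those pairs cross the depth sets and these libraries do not. On log2(TPM + 1) 73.9% were higher in place of 62.5%.

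Passage 2 endothelial cells derived from H1 were compared with HUVEC, to describe how endothelium grown from H1 differs from a primary endothelium. The collagen gene COL5A3 was at least 685-fold higher in the H1-derived cells. TMEM178 and FILIP1 had ratios of 1268 (95% counting interval 350.3 to 10484) and 882 (301 to 4284), and the neural tubulin gene TUBB2B stood 9.20 log2 higher. PRSS2 and PRSS3, which share reads, stood at least 294-fold higher and at least 205-fold lower, and the read-through symbol NME1-NME2 at least 562-fold lower. The proteoglycan gene SRGN had a ratio of 1009 (345 to 4892) in favour of HUVEC, SPOCK1 of 1312 (235 to 51857) and HHIP of 670.1 (229 to 3251). The arterial list had a median of 2.07, the HOXA cluster -3.49 with a bounded median of -2.76, and proliferation genes -2.13. Within the HVMP and AHP duplicates the sizes were 1.24 and 0.69, 0.38 and 0.93, and 0.18 and 0.06. As many as 2525 genes met the size rule, 1352 higher and 1173 lower, but the split depended on the scale, and on log2(TPM + 1) 78.8% were higher in place of 53.5%. No other comparison of single libraries had as many. Even so, each of these 2 libraries correlated most with the other (Pearson r = 0.817 across genes). On the first principal component of all 17, which held 30.5% of the variance, they lay near each other, at 196.8 and 190.6. Both stood apart from the remaining libraries on that component.

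Across all genes tested, the libraries of duplicates were not always nearest to each other. HVMP replicate 1 and replicate 2 each correlated most with the VE-cadherin-positive cells of day 4 (Pearson r = 0.959 and 0.970 across genes), and with each other at 0.956. AHP replicate 1 and replicate 2 each correlated most with the CD41a-positive cells (0.986 and 0.967), and with each other at 0.959. HEP and non-HEP correlated most with each other (0.970), as did the CD45-negative and CD45-positive progenitors (0.968). The counts of both duplicate pairs differed beyond sampling noise, with a chi-square per degree of freedom of 88.6 for HVMP and 76.1 for AHP, which does not tell technical from biological spread.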

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

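Of the counts that alternatives gave, 109 stayed within 1.5 times those above and 51 moved. DESeq2 called 1167 genes for AHP against HVMP, 235 for HVMP against KDR-dim mesoderm, 411 against posterior mesoderm, 7 for VE-cadherin-positive cells against HVMP, 292 for AHP against HEP, 1 for CD41a-positive cells against AHP and 301 for cores against HVMP. Limma on log2(TPM + 1) called 169 for AHP against HVMP, with 46.2% higher in place of 31.8%, and 21, 125 and 11 for HVMP against KDR-dim mesoderm, HVMP against posterior mesoderm and cores against HVMP. It called 5 lists in place of 8 for CD41a-positive cells and 6 in place of 10 for cores. With no filter on low counts edgeR called 59 genes for HVMP against posterior mesoderm and 10 for cores, and camera called 7 lists in place of 11 for HVMP against KDR-dim mesoderm, 4 in place of 7 for VE-cadherin-positive cells, 4 in place of 8 for CD41a-positive cells and 5 in place of 10 for cores. With only the libraries of the 2 groups in the fit edgeR called 64 genes for HVMP against posterior mesoderm, 126 for AHP against HEP and 1 for CD41a-positive cells. With a block for replicate number 2971 genes passed for AHP against HVMP, 42.3% of them higher, the largest change of this count. The differences within the HVMP and AHP pairs correlated across genes at r = 0.51. In both pairs replicate 1 is deep and replicate 2 shallow, so the block cannot be told from the depth set, and the labels do not state a pairing. The block also left fewer residual degrees of freedom than the main fit.

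Leaving out 1 library of a duplicated group left 1 pair of duplicates, so all the spread came from that pair with 1 residual degree of freedom. Lone libraries were assumed to vary like it. The counts then ranged from 663 to 1383 for AHP against HVMP, 225 to 394 for HVMP against KDR-dim mesoderm, 321 to 998 against posterior mesoderm, 38 to 57 for VE-cadherin-positive cells, 1 to 25 for AHP against HEP, 0 to 2 for CD41a-positive cells and 342 to 522 for cores. Lists called ranged from 7 to 14 for HVMP against KDR-dim mesoderm and 6 to 12 for VE-cadherin-positive cells. Without AHP replicate 1 44.2% of the genes called for AHP against HVMP were higher. The cause of these moves was not tested.

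Chosen after seeing the data were a term for the depth set, the size-rule counts within a depth set, and removal of the mean deep-minus-shallow difference. The term left fewer residual degrees of freedom than the 2 of the main fit. With the depth set as a term edgeR called 653 genes for HVMP against KDR-dim mesoderm, 476 against posterior mesoderm, 317 for AHP against HEP and 2438 for cores, and camera called 12 lists for VE-cadherin-positive cells. Against the duplicate of the other depth set, genes that met the size rule numbered 484 for KDR-dim mesoderm, 1288 for posterior mesoderm, 292 for VE-cadherin-positive cells, 850.0 for HEP, 149 for CD41a-positive cells and 998 for cores. With the deep-minus-shallow difference removed, 606 genes met the size rule for the day 8 CD235a/CD41a-positive against CD45-negative cells, 234 higher and 372 lower, and 1281 for posterior mesoderm against H1.

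In the comparisons of single libraries, a minimum of 10 counts gave 429 genes for HEP against VE-cadherin-positive cells, 222 for HEP against non-HEP, 478 for day 8 against day 5 and 297 for CD45-positive against CD45-negative cells. Differences of log2(TPM + 1) gave 60, 156 and 92 for the last 3. By them 87.3% were higher in HEP than in VE-cadherin-positive cells in place of 74.9%, 69.2% at day 8 than at day 5 in place of 79.8%, 16.2% in CD235a/CD41a-positive than in CD45-negative cells in place of 44.1%, 73.9% in CD45-positive cells in place of 62.5%, and 78.8% in passage 2 cells than in HUVEC in place of 53.5%. The median over all genes shifted with TPM by 0.13 for AHP against HVMP, -0.12 and -0.11 for HVMP against KDR-dim and posterior mesoderm, and -0.2 for AHP against HEP. It shifted by 0.3 for HEP against VE-cadherin-positive cells, -0.38 for day 8 against day 5, -0.54 for CD235a/CD41a-positive against CD45-negative cells and 0.55 for passage 2 cells against HUVEC.

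For AHP against HVMP the medians that changed sign were those of lists camera did not call. Limma on TPM gave pluripotency 0.02 and sort genes 0.47, the stricter filter and the fit of 2 groups gave paraxial mesoderm -0.46 and -0.42, and the block for replicate number gave sort genes 0.33. Leaving out 1 library gave ranges of -0.68 to 0.07 for pluripotency, -0.6 to 0.68 for paraxial mesoderm, -0.46 to 0.95 for hematovascular factors, -0.38 to 2.21 for endothelial genes, -1.08 to 0.06 for arterial genes, -1.22 to 0.02 for venous genes, 0 to 1.88 for endoderm, -0.04 to 0.08 for hypoxia and -0.95 to 1.75 for sort genes. For the VE-cadherin-positive cells CDH5 ranged from -1.51 to 4.76, and was 1.01 with limma and 2.38 with the depth set as a term. For cores the median of endoderm genes was -0.55 with the stricter filter, which removed the genes with the lowest counts. Camera was not run with DESeq2, and the stricter filter left no gene of the lymphoid list for AHP against HVMP.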

Other observations

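The duplicates of HVMP differed in endothelial transcripts, and both tests of this pattern were chosen only after the result was seen. All 20 genes of the endothelial list were higher in replicate 1, among them CDH5 (51.3 against 0.63 TPM), ESAM (35.6 against 1.21 TPM) and KDR (1261 against 349 TPM), with a median difference of 2.26 log2. The depth set alone could give such a gap, but between the AHP duplicates, which differ in depth set too, the median was 0.13, and the gap per gene between the pairs was 2.44 log2 (bootstrap 95% interval over genes 2.05 to 3.16). Cells like the VE-cadherin-positive library of day 4 could also have been carried into replicate 1. Cells of that kind alone would give the same share for endothelial and blood genes. The share needed was instead 1.15 by the median of 7 endothelial genes and 0.05 by 11 blood genes. Each gene's difference within the AHP duplicates was removed first (2.11 and 0.11 without that). Their ratio was 21.55 (bootstrap 95% interval over genes 5.3 to 1166.41), unstable because the blood median lay near 0. Shares ranged from 0.37 to 7.5 over the endothelial genes and from -0.48 to 0.9 over the blood genes. The interval takes no account of spread between libraries. The column header of replicate 2 says CD31-negative, that of replicate 1 does not name CD31, and both libraries are labelled EMHlin-negative, so a difference in the sort, endothelial cells of another kind or a difference in stage remain open and were not tested.

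The differences within the 2 duplicate pairs were alike, and of the tests of this pattern the one on GC content was written before its result was seen and the one on read-through genes after. Across genes the HVMP and AHP differences correlated at r = 0.51, and 85 genes met the size rule (4-fold and 50 counts) in both pairs, 84 of them in the same direction. Replicate 1 was deep and replicate 2 shallow in both pairs. A shared culture or run therefore cannot be told from the depth set as a source of this likeness, and neither was tested. A trend with GC content or transcript length could give this, but after its removal the correlation was 0.49 over 13404 genes. Genes with a read-through symbol, whose reads are split with their neighbours, made up 3.57% of the 84 (3 genes, exact 95% interval 0.743 to 10.1%) and 0.19% of all genes tested (Fisher's exact test, unadjusted p = 0.000524). These symbols were thus in excess but few. The neighbours that share their reads, and genes with near-identical copies, were not counted, so the test cannot say how much uncertain reads contributed. IAH1, chosen after its values were seen, was 0, 0.28, 0 and 0.24 TPM in HVMP replicate 1, KDR-dim mesoderm, the day 5 CD41a-positive cells and AHP replicate 1, and 7.47 to 95.2 TPM elsewhere.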
